A study of Mus musculus with 7 samples.

How the data were processed

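The series holds poly(A) RNA sequencing of microdissected left ventricles from 7 mouse embryos at embryonic day 12.5, 5 control and 2 labelled mutant. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, RNA was extracted with TRIzol and a column kit, libraries were made with a TruSeq RNA kit of the kind that does not mark strand, and single-end reads were sequenced on a HiSeq2500.

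The first deposited table holds whole-number read counts per gene symbol and library, with no normalization. Per the submitters' processing notes the genome build was mm10 and the tools were TopHat2 2.1.1, featureCounts, R 3.3.2, edgeR 3.16.5 and limma 3.30.13. Their roles, the gene annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here. The second deposited table gives the authors' own comparison per gene as a log fold change, taken as log2 from its closeness to the values computed here, with a p-value and a false discovery rate. Per the file headers it does not name the test. Every listed false discovery rate was at most 0.05, so the table is a list of significant genes.

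Library totals were 23189496, 20892166, 22297169, 20385656 and 24440806 counts in control replicates 1 to 5 and 20268208 and 22680280 in mutant replicates 1 and 2. The 10 most abundant genes took 7.01% to 7.67% of the counts. Counts of 2 libraries of a group differed by 10.5 to 33.7 times the sampling noise (chi-square per degree of freedom), so no library was a copy of another of its group. Without strand information, reads of overlapping or antisense genes cannot be told apart. Genes with near-identical copies are uncertain, and 26 genes shared an identical row of over 100 counts with another gene, 0 of them called.

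Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 14691 of 23337. Counts were normalized by TMM factors of 0.988 to 1.009 and tested with glmQLFit and glmQLFTest with robust estimation and genotype as the only term. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05, unless stated to be over a list. The common biological coefficient of variation was 0.128, with 5 residual and a median of 5.5 prior degrees of freedom. The SE of a log2 fold change was its size divided by the square root of the F statistic. CPM values use the TMM-scaled library totals, and list scores are means of log2 CPM with a prior count of 2.

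Gene lists were tested with limma's camera with a preset correlation of 0.01, Benjamini-Hochberg adjusted over 28 lists, and again with an estimated correlation and with fry. The lists, the test, its design, most alternatives and the rule for named genes were fixed before the data were examined. The rule took Tbx5, 7 genes known to depend on TBX5, the 8 called genes of lowest adjusted p and the 4 of largest change in each direction, up to 4 called genes per list, up to 2 abundant genes as values in lists with fewer than 2 called, and the genes that report sex. The genes of lowest p and largest change needed a mean of at least 1 CPM and both libraries labelled mutant outside the control range, and symbols of predicted genes were passed over. The values of 3 genes taken by the rule are not reported here. A list of 49 tested interferon-induced genes was made after the data were seen.

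The test was tested on simulated data with the means, dispersions and totals of the 14691 genes and 200 changed genes. The changed genes were drawn only from genes above a minimum mean count, and genes varied independently of each other. Recovery among weaker genes was therefore not measured, nor the effect of structure shared by libraries. For 5 control against 2 mutant libraries the test recovered 59.7% of genes changed by 1.5 times, 85.1% of those changed by 2 times and 100% of those changed by 4 times. Over 5 simulated data sets 7.56% of calls were false, above the nominal share. With no change simulated, the quasi-likelihood test and limma-voom called 0 genes and the edgeR likelihood ratio test 14.

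Alternatives were DESeq2 1.42.0 and its size factors, limma-voom, other scalings and filters, other thresholds, the absence of robust estimation, each library left out, the replicate number as a block, and sex or haemoglobin as a covariate. The edgeR likelihood ratio test, the 5 libraries with Xist over 10 CPM, and the removal of 2 libraries together were chosen after seeing the data. The table held no mitochondrially encoded genes, so the alternative planned for these and haemoglobin removed haemoglobin genes only. Gene positions came from RefSeq GRCm38.p6, which matched 23061 of the 23337 symbols, and exon lengths from GENCODE. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.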

Results

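Gene expression was measured by poly(A)-selected RNA sequencing in the left ventricle of mouse embryos at embryonic day 12.5. The mothers had received tamoxifen 1 day earlier. Tamoxifen activates CreERT2, a recombinase expressed here from the Rosa26 locus, which removes DNA between loxP sites. Of the 7 libraries, 5 came from controls with unmodified Tbx5 alleles and 2 from embryos labelled mutant, with 2 loxP-flanked Tbx5 alleles. Tbx5 encodes a T-box transcription factor of the developing heart. The count table held 23337 gene symbols, and the library totals ran from 20385656 to 24440806 counts in the controls and were 20268208 and 22680280 in the libraries labelled mutant. The single comparison of the design asked which left ventricular transcripts differ after deletion of Tbx5. The labels name no litter, sex or batch, and nothing in them says that the embryos came from separate litters, so p-values here measure only the spread between these samples.

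The Tbx5 gene itself, on chromosome 5 at 119796514 to 119885220 of the mm10 (GRCm38) assembly, was not lower in the libraries labelled mutant. Its counts were 1542, 1695, 2165, 1297 and 1840 in control replicates 1 to 5, and 1894 and 2602 in mutant replicates 1 and 2. In CPM, the counts scaled to a common library total, this was 76.9 ± 13.7 (SD, n = 5) in the controls and 104 ± 14.1 (SD, n = 2) in the libraries labelled mutant. The log2 fold change was 0.43 with a standard error (SE) of 0.15, and the adjusted p was 0.181 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. An exact two-sided permutation test over the 21 splits of the libraries gave p = 0.143, where the smallest possible value was 0.0476. A count over the whole gene includes exons outside the deleted part, so it does not check the deletion. The genotypes therefore rest on the labels, and every direction given here is that of the libraries labelled mutant against the controls.

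Xist, the RNA of the inactive X chromosome, was near 0 in control replicates 1 and 3, at 0.689 and 1.09 CPM. It lay between 311 and 509 CPM in the 5 other libraries, both libraries labelled mutant among them. The 16 Y-linked genes of the table, among them Ddx3y, Eif2s3y, Kdm5d and Uty, had 0 counts in every library and gave no second reading of sex. The 2 controls with little Xist thus had no counterpart among the libraries labelled mutant.

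**Figure D1:**
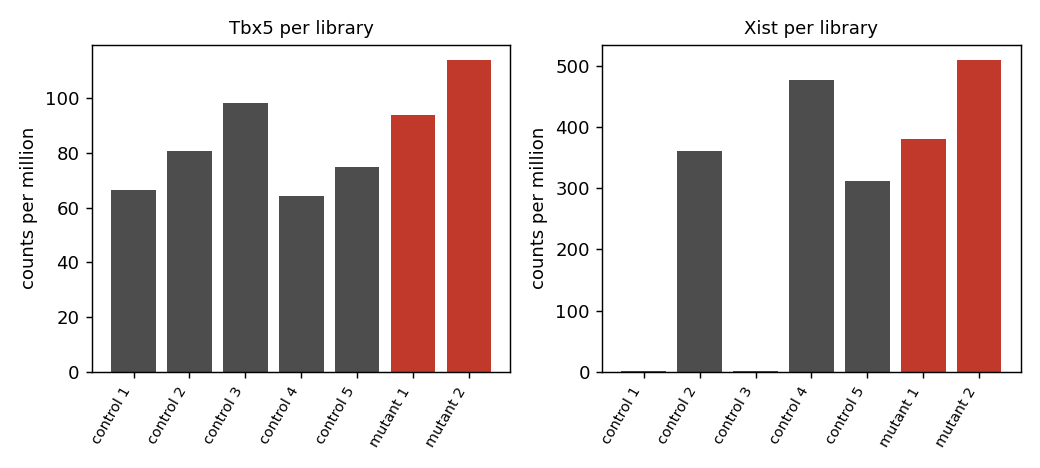
Tbx5 (left) and Xist (right) in CPM, 1 bar per library, with the 5 controls in grey and the 2 libraries labelled mutant in red. Tbx5 lay at 93.9 and 114 CPM in the libraries labelled mutant, against 64.2 to 98.3 CPM in the controls, and Xist was near 0 in control replicates 1 and 3 only.

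The clearest falls in the libraries labelled mutant were in Nppb, Angpt1 and Cthrc1. Nppb, which encodes the B-type natriuretic peptide, fell from 157 ± 14.1 CPM (SD, n = 5) to 67.4 ± 3.53 CPM (SD, n = 2). Angpt1, a ligand of the endothelial receptor Tie2, fell from 53.2 ± 5.78 to 21.6 ± 1.36 CPM, and Cthrc1, a secreted matrix protein, from 12.4 ± 2.36 to 1.48 ± 0.625 CPM, with the same numbers of libraries. The clearest rises were in Strn, which encodes the scaffold protein striatin, from 52.1 ± 6.72 to 120 ± 4.58 CPM, and in Lmo7, a LIM-domain protein of cell junctions, from 277 ± 20.7 to 536 ± 35.8 CPM. The adjusted p was 0.00208 for each of these 5 genes by the edgeR quasi-likelihood test.

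Of 14691 genes tested, 200 (1.36%) passed an adjusted p of 0.05 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Of these, 68 were higher and 132 lower in the libraries labelled mutant, while without mutant replicate 1 the numbers were 147 higher and 61 lower. At an unadjusted p under 0.05 there were 2587 genes, 1188 higher and 1399 lower. Both libraries labelled mutant lay outside the range of the 5 controls for all 200 called genes and for 2964 tested genes (20.2%), where chance gives 9.52%. For a called gene, leaving out 1 library could therefore hardly turn its direction. The count rested on single libraries: it was 12 without mutant replicate 2, 80 without control replicate 1 and 68 without control replicate 2. It was 60 with sex read from Xist as a covariate and 66 among the 5 libraries that expressed Xist. Control replicate 5 and mutant replicate 2 together differed from the 5 other libraries by 647 called genes, 0 of them among the 200. With both left out, 52 genes were called. Nppb, Angpt1, Cthrc1, Stbd1, Cdo1, Meox1, Strn and Lmo7, 8 of the 200, were called in all 22 alternative fits, among them those without any one library. Of the 46 called genes reported under the fixed rule for named genes, the other 38 lost their call without mutant replicate 2, 16 without mutant replicate 1, and 16, 17, 10, 5 and 3 without control replicates 1 to 5, while none changed direction.

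Among the other genes with the lowest adjusted p, those that fell included Stbd1, a glycogen-binding protein, with a log2 fold change of -0.95 (SE 0.09), and Cdo1, cysteine dioxygenase, with -1.23 (SE 0.13). Meox1, a homeobox transcription factor, changed by -1.62 (SE 0.18) and Fhl2, a LIM-domain protein of cardiac muscle, by -1.24 (SE 0.14). Among those that rose were Sntb1, a syntrophin of the dystrophin complex, at 1.11 (SE 0.13), and Aqp4, a water channel, at 1.04 (SE 0.13). Rragd, a Rag GTPase of the mTORC1 pathway, rose by 0.83 (SE 0.10), Parm1 by 0.79 (SE 0.10), Usp13, a deubiquitinating enzyme, by 0.70 (SE 0.08) and Epb4.1l3, a membrane skeleton protein, by 0.69 (SE 0.08). Adjusted p for these 10 genes lay between 0.00208 and 0.00637 (edgeR quasi-likelihood test, Benjamini-Hochberg). Without mutant replicate 2 the calls of Fhl2, Sntb1, Aqp4, Rragd, Parm1, Usp13 and Epb4.1l3 were lost, at adjusted p of 0.0638 to 0.0673 by the same test.

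The largest falls among called genes of at least 1 CPM were in Ntsr1, Frem3, Sln and Gal. Ntsr1, a neurotensin receptor, was at 4.28 ± 1.82 CPM (SD, n = 5) in the controls and 0.121 ± 0.109 CPM (SD, n = 2) in the libraries labelled mutant. Sln, which encodes sarcolipin, an inhibitor of the calcium pump of the sarcoplasmic reticulum, was at 9.65 ± 3.83 against 0.531 ± 0.441 CPM. Gal, the neuropeptide galanin, was at 1.94 ± 0.99 against 0.14 ± 0.0123 CPM, and Frem3, an extracellular matrix protein, at 4.52 ± 2.26 against 0.175 ± 0.248 CPM. The largest rises among called genes of at least 1 CPM were smaller: Adra1d, an alpha-adrenergic receptor, by a log2 fold change of 1.85 (SE 0.27), Kcnj12, an inward rectifier potassium channel, by 1.36 (SE 0.20), Acss1, a mitochondrial acetyl-CoA synthetase, by 1.30 (SE 0.21) and Zcchc12 by 1.23 (SE 0.20). Each of these 8 genes lost its call without mutant replicate 2, with adjusted p of 0.0981 to 0.276 by the edgeR quasi-likelihood test, and Frem3, Sln and Gal also without mutant replicate 1 (0.0739, 0.0547 and 0.0863). Frem3 also lost it without control replicate 1 (0.0561) or 3 (0.0516), Gal without control replicate 1 (0.0746), 2 (0.0607) or 3 (0.0531), and Zcchc12 without control replicate 2 (0.0575).

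**Figure D2:**
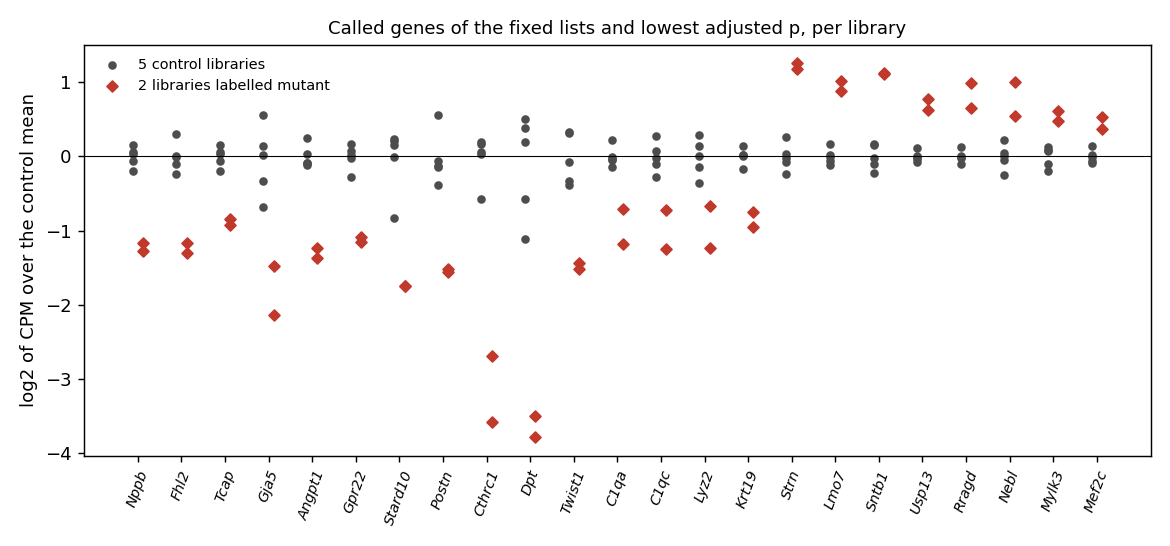
Each point is 1 library's CPM over the mean of the 5 controls, on a log2 scale, for 23 called genes (grey circles, controls; red diamonds, libraries labelled mutant). Both libraries labelled mutant lie outside the control range for every gene shown, as for Nppb at 69.9 and 64.9 CPM against 137 to 174 CPM in the controls.

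Several genes described before as depending on TBX5 were measured whether called or not. Gja5, which encodes connexin 40, a gap junction protein of conduction tissue and trabeculae, fell from 140 ± 45.2 CPM (SD, n = 5) to 40.9 ± 13 CPM (SD, n = 2). Its adjusted p was 0.0471 by the edgeR quasi-likelihood test, and it was not called without control replicate 1 (0.0631), control replicate 2 (0.0716), mutant replicate 1 (0.14) or mutant replicate 2 (0.243). Nppa, the atrial natriuretic peptide, had a log2 fold change of -0.16 (SE 0.19) and Id2 -0.19 (SE 0.17). The values were 0.32 (SE 0.31) for the myosin heavy chain Myh6, 0.20 (SE 0.18) for the ryanodine receptor Ryr2 and 0.19 (SE 0.15) for the calcium pump Atp2a2. None of these 5 passed the test, with edgeR quasi-likelihood adjusted p of 0.533 to 0.698. Within the fixed list of 20 such genes, 4 were called lower, among them Gja5, Cacna1g and Sln, and none higher, and 5 were lower and 1 higher when adjusted over the list alone. The list as a whole did not pass limma's camera test (adjusted p = 0.0932). Its number of called genes was 0 without either mutant replicate and 2 without control replicate 1 or 2.

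Some atrial marker genes were lower in the libraries labelled mutant. Of 21 tested, 7 were called lower and none higher, 5 had a positive log2 fold change, and the median log2 fold change of the list was -0.60. Angpt1 and Sln, given above, were among the 7. Stard10 fell from 25.0 ± 6.41 to 7.48 ± 0.0005 CPM and the orphan receptor Gpr22 from 37.6 ± 4.15 to 17.3 ± 0.582 CPM (SD, n = 5 and n = 2). Camera gave the list an adjusted p of 2.72e-06 with the preset correlation of 0.01, and the adjusted p was 0.627 with an estimated correlation. When adjusted over the list alone, 10 genes were lower and 1 higher, the latter being Tbx5 itself, which belongs to this list (log2 fold change 0.43). Control replicate 4 was the lowest control for 6 of the 7 called markers, and its list score, the mean log2 CPM, was 5.58 against 6.09 to 6.25 in the other controls and 5.17 and 5.31 in the libraries labelled mutant. Without mutant replicate 1 the number of called markers was 2, and without mutant replicate 2 it was 1.

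Of 31 tested genes of cushion mesenchyme, fibroblasts and extracellular matrix, 9 were called lower and none higher, 29 of the 31 had a negative log2 fold change, and the median was -0.67. Postn, which encodes the matrix protein periostin, fell from 433 ± 116 to 149 ± 2.71 CPM (SD, n = 5 and n = 2), and Dpt, dermatopontin, from 10.9 ± 4.5 to 0.878 ± 0.12 CPM. Twist1, a transcription factor of mesenchyme, fell from 12.8 ± 3 to 4.59 ± 0.173 CPM. The list passed camera at an adjusted p of 6.69e-14, with an adjusted p of 0.394 with an estimated correlation, and 21 genes were lower when adjusted over the list alone. The number called was 3 without mutant replicate 1 and 1 without mutant replicate 2. Of 33 markers of endocardium and endothelium none was called, the median was -0.05, and camera gave an adjusted p of 0.124. Eng and Cdh5, both endothelial surface proteins, had log2 fold changes of 0.19 (SE 0.18) and -0.04 (SE 0.18).

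All 23 tested macrophage and leukocyte genes had a negative log2 fold change, with a median of -0.70, and 3 were called lower, C1qa and C1qc, subunits of the complement protein C1q, and the lysozyme gene Lyz2. Lyz2 fell from 61.1 ± 10.3 to 32.1 ± 8.83 CPM, C1qa from 17.9 ± 1.72 to 9.46 ± 2.18 CPM and C1qc from 23.1 ± 3.34 to 11.8 ± 3.01 CPM (SD, n = 5 and n = 2). Camera gave an adjusted p of 6.04e-11, and the adjusted p was 0.627 with an estimated correlation; 15 genes were lower when adjusted over the list alone. None was called without mutant replicate 2, control replicate 1 or control replicate 2, 1 was called without control replicate 3, and none among the libraries that expressed Xist. Of 19 epicardial genes, Krt19, a keratin, was called lower at a log2 fold change of -0.85 (SE 0.10), with a median of -0.09 and a camera adjusted p of 0.0665. Upk3b and Podxl, also of the epicardial list, had log2 fold changes of -0.48 (SE 0.29) and 0.05 (SE 0.12). The epicardial list had 4 genes lower when adjusted over the list alone, and the call of Krt19 was lost without mutant replicate 2 (adjusted p 0.0681, edgeR quasi-likelihood).

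Sarcomere genes moved in both directions. Of 45 tested, 3 were called higher and 3 lower, and 16 were higher and 7 lower when adjusted over the list alone. Nebl, which encodes nebulette, rose from 103 ± 12.2 to 179 ± 40.4 CPM, and Mylk3, the cardiac myosin light chain kinase, from 222 ± 20.7 to 322 ± 21.3 CPM (SD, n = 5 and n = 2). Tcap, which encodes the titin-capping protein telethonin, fell from 91.3 ± 8.06 to 49.5 ± 2.24 CPM, and Fhl2 is described above. The list median was 0.22 and camera found it higher at an adjusted p of 0.0184, with an adjusted p of 0.627 with an estimated correlation. None was called without mutant replicate 2, 2 without control replicate 1 or 2, 4 without mutant replicate 1 and 10 without control replicate 5.

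Of 33 calcium handling genes, Camk2a, a calcium-calmodulin kinase, was called higher at a log2 fold change of 0.55 (SE 0.11). Sln and Cacna1g, a T-type calcium channel at -1.41 (SE 0.28), were called lower. The list median was 0.20 and camera found it higher (adjusted p = 0.0372, and 0.627 with an estimated correlation), while its mean was -0.014, so the mean and the test differed in sign. The calcium handling score was 5.99 in mutant replicate 1, below every control, and 6.31 in mutant replicate 2, above every control. Among 37 cardiac transcription factors, Mef2c, a MADS-box factor, rose from 85.4 ± 5.65 to 117 ± 8.77 CPM (SD, n = 5 and n = 2). That list had a median of 0.17, a mean of -0.0072 and a camera direction upwards (adjusted p = 0.0372, and 0.627 with an estimated correlation), again with opposite signs. Its score was 5.12 in mutant replicate 1 and 5.34 in mutant replicate 2, both inside the control range of 5.10 to 5.42. Tbx20 and Hopx, of the same list, had log2 fold changes of -0.10 (SE 0.15) and 0.27 (SE 0.09) and were not called. The calcium handling list did not pass without control replicate 1, 2, 3 or 4 (camera adjusted p of 0.0587, 0.0805, 0.0643 and 0.0709), nor among the libraries that expressed Xist (0.0783), and its direction turned without mutant replicate 2 (median -0.02). The transcription factor list did not pass without control replicate 1, 3 or 4 or mutant replicate 2 (0.0587, 0.132, 0.0709 and 0.398), nor with the replicate block (0.068) or among the libraries that expressed Xist (0.219). Adjusted over the list alone, 10 calcium handling genes were higher and 4 lower, as were 11 and 6 transcription factors. Without mutant replicate 2 no gene of either list was called, and 1 calcium handling gene was called without control replicate 1 or 3. Mef2c also lost its call without control replicate 1, 2, 3 or 4 or mutant replicate 1, at edgeR quasi-likelihood adjusted p of 0.0988, 0.0976, 0.0704, 0.0541 and 0.0501.

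Of 40 tested genes of fatty acid oxidation and the citric acid cycle, 36 had a positive log2 fold change, with a median of 0.20, and 1, the coactivator gene Ppargc1b, was called higher at 0.62 (SE 0.13). Idh2, an enzyme of the citric acid cycle, had a value of 0.06 (SE 0.10). Camera found the list higher at an adjusted p of 1.41e-07, the adjusted p was 0.627 with an estimated correlation, and 8 genes were higher when adjusted over the list alone. The call of Ppargc1b was lost with any 1 library but control replicate 4 left out, at edgeR quasi-likelihood adjusted p of 0.05 to 0.265. Nuclear genes of oxidative phosphorylation had a median of 0.04 with none of 53 called (camera adjusted p = 0.124), and Atp5b and Atp5a1 of that list were at 0.19 (SE 0.09) and 0.21 (SE 0.08). Of 36 genes of glycolysis and low oxygen, Ndrg1 was called lower at -0.72 (SE 0.14), while Aldoa and Ldha were at -0.0040 (SE 0.10) and -0.06 (SE 0.11). That list had a median of 0.02, a mean of -0.0035 and a camera adjusted p of 0.879, and 3 genes were higher and 1 lower when adjusted over the list alone. The call of Ndrg1 was kept without control replicate 3 and lost without any other 1 library.

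No single gene for a cytoplasmic ribosomal protein was called. All 77 tested had a negative log2 fold change, with a median of -0.33, and camera found the list lower at an adjusted p of 3.13e-18, against an adjusted p of 0.627 with an estimated correlation. Rpsa and Rplp0 had log2 fold changes of -0.31 (SE 0.12) and -0.26 (SE 0.10). The list score was 9.51 and 9.16 in mutant replicates 1 and 2, and 9.73, 9.63, 9.76, 9.73 and 9.47 in control replicates 1 to 5, so that control replicate 5 lay below mutant replicate 1.

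Cell cycle genes had a median of 0.07 with none of 50 called. Camera found the list higher (adjusted p = 0.0184), with an adjusted p of 0.627 with an estimated correlation. It did not pass without control replicate 5 (0.0538), and its direction turned without mutant replicate 1 (median -0.08). Top2a and Cdk4 were at 0.03 (SE 0.12) and -0.15 (SE 0.09). Of 28 cell cycle inhibitors and p53 target genes, Wee1, a kinase that delays mitosis, was called higher at 0.43 (SE 0.08), and the list did not pass (adjusted p = 0.123), with 2 genes higher and 0 lower when adjusted over the list alone. Cdkn1c and Ccng1, of the same list, had values of -0.06 (SE 0.12) and 0.30 (SE 0.14). Of 46 genes of BMP, WNT, FGF and Notch signalling, Fgf12, an intracellular FGF family member, and Sfrp2, a WNT antagonist, were called lower at -2.28 (SE 0.38) and -1.48 (SE 0.30). That list had a median of -0.12 and a camera adjusted p of 0.0372, with an adjusted p of 0.627 with an estimated correlation. It did not pass without control replicate 1, 2 or 5 or mutant replicate 1 (0.0587, 0.0805, 0.131 and 0.607), nor with the haemoglobin covariate (0.1) or without genes shared with another list (0.116). Adjusted over the list alone, 9 of its genes were lower and 1 higher. The calls of Wee1, Fgf12 and Sfrp2 were lost without mutant replicate 2 and without control replicate 1 or 2, that of Wee1 also without control replicate 3 or 4 or mutant replicate 1, and that of Sfrp2 also without control replicate 3 or 5 or mutant replicate 1.

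**Figure D3:**
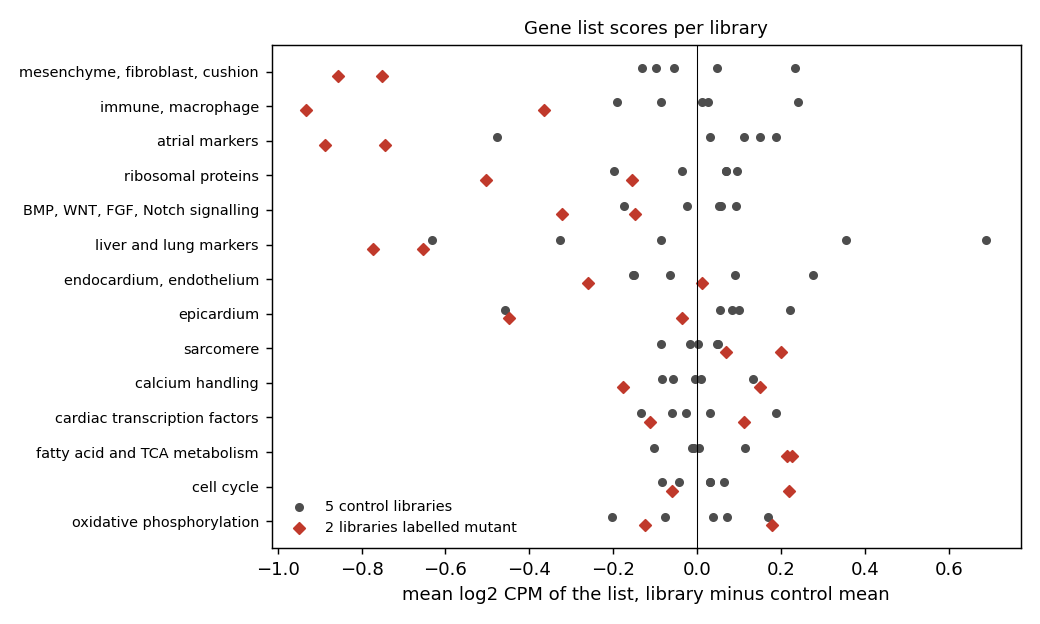
The horizontal axis gives each library's mean log2 CPM over a gene list minus the mean of the 5 controls (grey circles, controls; red diamonds, libraries labelled mutant). Both libraries labelled mutant lie below every control for mesenchyme, macrophage and atrial genes, while for ribosomal proteins control replicate 5, at 9.47, lies below mutant replicate 1, at 9.51.

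Adjusted over each list alone, genes higher and lower numbered 2 and 5 of the trabecular, 2 and 4 of the compact layer, 2 and 3 of the right ventricular and outflow, 4 and 9 of the ion channel, and 0 and 1 of the smooth muscle list. Nppb and Gja5 were the 2 of 20 trabecular genes called, both lower, and the list median was -0.05 (camera adjusted p = 0.275). None of 19 compact layer genes was called (median -0.10, adjusted p = 0.161), and Ccnd2 of that list was at 0.13 (SE 0.11). Of 14 right ventricular and outflow genes, Rspo3, a WNT agonist, was called lower at -1.38 (SE 0.23) and Mef2c higher (median -0.23, adjusted p = 0.161). Of 32 ion channel and gap junction genes, Kcnj12 was called higher and Gja5 lower (median -0.16, adjusted p = 0.279). No smooth muscle or mural gene of 15 was called (median -0.18, adjusted p = 0.551), with Acta2 at 0.61 (SE 0.25) and Des at 0.29 (SE 0.13). No erythroid gene of 23 was called (median -0.23, adjusted p = 0.623). Hbb-y of that list was at -0.34 (SE 0.30) and Hba-a1, whose counts equalled those of Hba-a2 in every library and are therefore uncertain, at 0.64 (SE 0.34).

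Adjusted over each list alone, 1 gene was lower and none higher in each of the lists of liver, lung and foregut, stress, hedgehog and histone genes. None passed in those of endothelium, erythroid cells, neural crest, the cell cycle, oxidative phosphorylation, the unfolded protein response and ribosomal proteins. Of 15 neural crest, neuronal and glial genes none was called (median -0.23, camera adjusted p = 0.16), with Hand2 at 0.07 (SE 0.09) and Erbb3 at 0.14 (SE 0.20). None of 8 liver, lung and foregut genes was called, and the list was lower by camera at an adjusted p of 0.0372 with a median of -1.12, and an adjusted p of 0.627 with an estimated correlation. It did not pass without control replicate 1 or 5 or mutant replicate 1 (0.0587, 0.0538 and 0.169). Its most abundant genes, Trf and Afp, were at -0.62 (SE 0.14) and -0.99 (SE 0.95), and Afp ranged from 0.285 to 4.60 CPM among the controls. Of 29 immediate early and stress genes Atf3, a stress-induced transcription factor, was called lower at -0.77 (SE 0.10), with Hspa8 at -0.04 (SE 0.10) and Jund at -0.06 (SE 0.13) (list median -0.06, adjusted p = 0.0932). No gene was called among 28 of the unfolded protein response (median -0.11, adjusted p = 0.0932), where Hspa5 was at -0.07 (SE 0.10) and Hsp90b1 at -0.15 (SE 0.10). None was called among 13 hedgehog genes (median -0.13, adjusted p = 0.417), with Cdon at 0.02 (SE 0.13) and Smo at -0.13 (SE 0.08). None was called among 12 histone genes (median -0.11, adjusted p = 0.548), with Hist1h1c at -0.06 (SE 0.12) and Hist3h2a at -0.48 (SE 0.11).

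In all, 11 of the 28 lists passed camera with the preset correlation, 5 higher and 6 lower. With an estimated correlation 0 passed, 1 list had an unadjusted p under 0.05 (mesenchyme, 0.0141), and by limma's fry test 1 passed. Lists that did not pass with all libraries but did with 1 left out were lower for endothelium without control replicate 3 (adjusted p 0.022) or mutant replicate 2 (0.00115), and for epicardium without control replicate 5 (0.00325) or mutant replicate 1 (0.00689). Oxidative phosphorylation passed as higher without control replicate 3 (0.0168) or mutant replicate 2 (9.7e-07). The list of genes depending on TBX5 passed as lower without control replicate 4 (0.0466) or mutant replicate 2 (0.00142). Ion channels (0.0148), trabecular (0.0204), compact (0.00309) and right ventricular and outflow genes (0.0253) did so without mutant replicate 2. Among the libraries that expressed Xist, endothelium passed as lower (0.0366) and oxidative phosphorylation as higher (0.00553). Epicardium passed as lower with the replicate block (0.0401) or the haemoglobin covariate (0.03), neural crest genes with the block (0.0369), and right ventricular and outflow genes without genes shared with another list (0.0368).

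The authors' deposited table listed 668 genes, 273 higher and 395 lower. All 668 had the same direction in the fit made here, and the largest difference between the log2 fold changes in the authors' deposited table and those computed here was 0.0323. Of the 200 called genes, 196 stood in the authors' deposited table. The other 4, named after their values were seen, were BC048943, Ms4a4d and Grm7, lower, and Mybpc3, cardiac myosin-binding protein C, higher at a log2 fold change of 0.43. The table was made from the same libraries and is not independent evidence.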

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

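The tests of reads from undeleted exons, of exchanged labels of 2 named libraries, of atrial tissue, of the share of other cells, of a shared tissue piece, of short transcripts and of variation between libraries, and the number of markers still called with the haemoglobin covariate, were chosen after the results were seen. The tests of other splits, of any exchanged pair of labels and of the log2 fold changes kept with the haemoglobin covariate were set out before theirs.

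A single control library stood far from the other controls in 5 of 115 sets of control values, where chance gives about 1 in 20. Cthrc1 was at 8.37 CPM in control replicate 4, against 12.7 to 14.2 CPM in the other controls. Postn was at 633 CPM in control replicate 1, against 332 to 416 CPM. Ndrg1 was at 26.9 CPM in control replicate 3, against 36.6 to 37.9 CPM. The atrial marker score was 5.58 in control replicate 4, against 6.09 to 6.25, and the epicardial score was 4.31 in control replicate 5, against 4.82 to 4.99.

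The labelled grouping gave 200 called genes and Tbx5 was not lower in it. Of the 21 splits of the 7 libraries into 5 and 2, 2 gave at least 200 genes, so chance cannot be excluded by this count; the highest other was 647, for control replicate 5 with mutant replicate 2, and the remaining splits gave 0 to 2. The 647 genes included 0 of the 200, and they point to a structure of the samples that the labels do not name. Control replicate 5 and mutant replicate 2 had the lowest 2 list scores for ribosomal proteins, the cell cycle, oxidative phosphorylation and epicardium. They had the highest 2 for calcium handling and transcription factors. This did not hold for mesenchyme, macrophage or atrial genes. Whether labels of a control and a mutant library were exchanged stays open. The score of genes depending on TBX5 was highest in control replicate 5 (6.50) and lowest in mutant replicate 1 (5.59), but each is 1 library. An exchange of control replicate 5 and mutant replicate 1 would not make Tbx5 lower, as it was higher by 0.226 on the log2 scale in control replicate 5 with mutant replicate 2, but with an SE of 0.216 this does not decide by a rule of 2 SE, which was set after the value was known in place of a rule by which any value above 0 counted against the exchange. Reads from Tbx5 exons outside the deleted part may account for a count that was not lower. They would not by themselves give the count ratio of 1.35, a difference that was not called. The gene counts do not separate exons and so do not decide the part of such reads or how complete the deletion was.

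The called atrial and mesenchymal genes were lower in both libraries labelled mutant. Against erythroid content as the whole reason, 6 of the 7 called atrial markers stayed called with haemoglobin as a covariate. As 189 of all 200 called genes did so too, the number is not particular to these markers. All 7 kept at least 0.5 of their log2 fold change, but did so in every fit, which decides nothing. A lower share of other cells stays open for the mesenchymal genes. The mesenchyme minus endothelium score was lower by a log2 value of -0.682 (control SD 0.236, exact two-sided permutation p = 0.0476, the smallest possible). Minus epicardium it was lower by -0.564 (control SD 0.262, exact two-sided permutation p = 0.143), with mutant replicate 2 inside the control range. The first difference argues only against an equal fall of all other cells, and an unequal fall was not tested. The pair was chosen after its list medians (-0.67 and -0.05) were seen, so its p is no independent evidence. The list medians of macrophage (-0.70), erythroid (-0.23), neural crest (-0.23), smooth muscle (-0.18) and epicardial genes (-0.09) were negative too. Atrial tissue in the dissections remains a candidate explanation that the test made cannot settle. Control replicate 4 was the lowest control for 6 of the 7 markers, as high as in 0.41% of 10000 random sets of like expression. Co-regulated genes of a ventricle could vary together in the same way, which genes drawn at random do not. Only the called markers were counted. Of all 21 tested, 16 had a negative and 5 a positive log2 fold change, among the latter Myl4 (0.08) and Myh6 (0.32), while Nppa was at -0.16. The same control was the lowest for 3 of the 9 called mesenchyme genes, which is too few libraries and genes to decide whether the same tissue piece carried both. The genotype on the labels stays open as the biological explanation for both groups.

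Ribosomal protein genes had a median log2 fold change of -0.33. Under-recovery of short transcripts may account for part of it and stays open: 22 other genes of like expression, each with an exon length of at most 1327 bp, the lower quartile of the ribosomal protein genes, had a median of -0.167 (quartiles -0.29 and -0.0553). Against it, the ribosomal protein genes longer than their median of 1781 bp had a median log2 fold change of -0.339, though the exon length of a gene is not that of its transcripts. Variation between libraries unrelated to genotype may account for it, since 1 of the 2 libraries labelled mutant lay below every control and control replicate 5 lay below the other, and 2 libraries are too few to decide. The genotype on the labels is not excluded either.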

How the results depend on the processing

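The likelihood ratio test, the Xist-expressing libraries and the joint removal of control replicate 5 and mutant replicate 2 were chosen after seeing the data. For each change below the cause was not tested, except that fewer libraries were fitted where libraries were left out and that thresholds act by construction. All 200 called genes kept their direction in every fit that gave them a value (3 had none at a minimum of 1 CPM in 2 libraries), and all with a value kept at least 0.5 of their log2 fold change. With 1 library left out a turn was hardly possible, as both libraries labelled mutant lay outside the control range for all 200. Scaling, the 1 CPM filter and the absence of robust estimation gave 192 to 207 genes. The test for a difference of sex by the log2 fold changes kept was set out before its result. Among Xist-expressing libraries 100% of the 200 genes kept direction and at least 0.5 of the log2 fold change, but as all did in every fit, this decides nothing. By a test chosen after the results were seen, sex read from Xist does not account for the 58 genes that stayed called among these libraries, and for the other 142 it stays open. Depth was alike in all libraries, and at this size 59.7% of simulated changes of 1.5 times were found among genes above a minimum mean count.

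Called genes in total, higher and lower numbered 586, 252 and 334 at an adjusted p under 0.1, and 97, 12 and 85 at an absolute log2 fold change of at least 1. They numbered 784, 350 and 434 with DESeq2 and 789, 326 and 463 with the likelihood ratio test. Voom gave 114 in total and 65 lower. With sex from Xist as covariate they numbered 60, 19 and 41, among Xist-expressing libraries 66, 17 and 49, and with control replicate 5 and mutant replicate 2 both left out 52, 15 and 37. The haemoglobin covariate gave 303 in total and 125 higher, and no filter but 1 count gave 120 higher. With 1 library left out the totals ran from 12 (without mutant replicate 2) to 277 (without control replicate 5), the higher from 3 to 147 and the lower from 9 to 183. Falls outnumbered rises in each of these fits but the one without mutant replicate 1, with 147 higher and 61 lower. Where 1 mutant library was left, it was assumed to vary like the controls.

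The labels do not say that replicate numbers pair the samples, and only 2 numbers are shared. Deviations of the same-numbered libraries from their group means correlated at 0.0775 and 0.0117 across genes. Deviations of 2 libraries from their mean mirror each other, so these values cannot rule pairing out. With the replicate block, 811 genes were called, 299 higher and 512 lower, with 1 residual degree of freedom, and the Tbx5 log2 fold change was 0.5002 (edgeR quasi-likelihood adjusted p 0.0156, against 0.0704 to 0.724 without any 1 library). Under the block Cdkn1c (0.0051), Cdon (-0.077) and Hist1h1c (0.091) changed sign.

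Of the 28 lists, 0 passed with an estimated correlation and 1 by fry, and 7 to 16 with 1 library left out. The signs of named genes that changed were all of uncalled genes. Aldoa was at 0.0043 with DESeq2 size factors, 0.0030 without haemoglobin genes, 0.0051 with no filter, 0.00098 with the 1 CPM filter and 0.0055 with DESeq2. Cdon was at -0.0087 with upper-quartile factors and -0.010 with the haemoglobin covariate. With sex as covariate Erbb3 was at -0.0025 and Hspa5 at 0.0070, and among Xist-expressing libraries Hspa5 was at 0.012 and Ldha at 0.00092. With control replicate 5 and mutant replicate 2 left out Ryr2 was at -0.062, Atp2a2 at -0.068, Podxl at -0.072, Aldoa at 0.14, Ldha at 0.027, Hspa8 at 0.046 and Jund at 0.23. List medians under a changed camera or fry direction were -0.014 for ion channels without shared genes, and 0.024 (fry) and 0.0043 (haemoglobin covariate) for glycolysis.

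With 1 library left out, signs turned for uncalled genes over these log2 ranges, most often between the fits without mutant replicate 2 and without mutant replicate 1: Ryr2 -0.098 to 0.45, Atp2a2 -0.11 to 0.45, Tbx20 -0.25 to 0.052, Eng -0.0025 to 0.37, Cdh5 -0.44 to 0.28, Podxl -0.096 to 0.18, Hand2 -0.0054 to 0.15 and Hist1h1c -0.14 to 0.013. The ranges were Top2a -0.14 to 0.20, Aldoa -0.15 to 0.14, Ldha -0.19 to 0.064, Hspa8 -0.14 to 0.073, Jund -0.32 to 0.17 and Cdon -0.054 to 0.082. Lists whose camera direction turned had medians of -0.017 to 0.45 for calcium handling, -0.27 to 0.056 for ion channels, -0.29 to 0.12 for trabecular and -0.15 to -0.055 for compact myocardium. The medians were -0.23 to 0.068 for endothelium, -0.34 to 0.12 for erythroid genes, -0.085 to 0.21 for the cell cycle, -0.10 to 0.19 for oxidative phosphorylation and -0.016 to 0.040 for glycolysis.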

Other observations

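The test of interferon-induced genes and the test of genes near Tbx5 were chosen after the results were seen.

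Of 49 tested interferon-induced genes, a group outside the fixed lists, 5 were called lower and none higher: Iigp1, an interferon-induced GTPase, at a log2 fold change of -2.25 (SE 0.35), Lgals3bp at -1.21 (SE 0.22), Uba7, the activating enzyme of ISG15, at -0.75 (SE 0.14), and H2-T9 and H2-T22 at -0.89 (SE 0.17) each. These 5 were named after their values were seen, and H2-T9 and H2-T22 are near-identical genes whose counts are uncertain. All 5 stood among the genes that prompted the list. Of the 42 members not seen before, 38 had a negative log2 fold change and 0 were called.

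A set-wide difference of interferon-induced genes may lie behind this, as the median log2 fold change of those 42 members was -0.653. Their scores were 2.73, 3.02, 3.01, 2.35 and 2.36 in control replicates 1 to 5 and 2.41 and 1.87 in mutant replicates 1 and 2, so mutant replicate 1 lay inside the control range. An exact two-sided permutation test of the scores gave p = 0.19, with a smallest possible value of 0.0476, while camera with the preset correlation gave an unadjusted p of 2.66e-07. The rule for this test first counted 1 mutant library inside the control range against the hypothesis, which the result met. The rule was changed to both libraries after the result was known, because 1 library excludes nothing, and the hypothesis is left undecided.

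Passenger DNA around the targeted allele could bring called genes near Tbx5. Within 10 Mb of Tbx5 on chromosome 5, 3 of 220 tested genes (1.36%) were called, against 195 of 14349 elsewhere (1.36%). Fisher's exact test gave p = 1, and with 3 genes a small excess would not be seen.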
